A study of Mus musculus with 12 samples.

How the data were processed

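The series holds 12 RNA sequencing libraries of interscapular brown fat, 1 per mouse, from wild-type C57BL/6J mice that were 14 weeks old after 4 weeks at 30, 22 or 6 °C, with 4 mice at each temperature, per the labels. Per the labels' protocols, total RNA was extracted with Qiazol and an RNeasy kit, treated to remove DNA, and made into libraries by standard Illumina methods. The authors deposited 1 table of raw read counts per Ensembl mouse gene, with no normalisation. FastQC 0.10.1, STAR 2.4.2a and edgeR 3.14.0 and the builds GRCm38 and mm10 are named, without roles, per the submitters' processing notes. The counting program, the annotation release, the strandedness of the libraries and any filter are not given in the sources used here, so reads of genes that overlap on opposite strands cannot be told apart. A numbered mouse was matched to its column for 10 libraries. The other 2 columns carry the letter of the 30 °C titles with numbers that match no title of that group. They were assigned to 30 °C by the letter alone and are called mice A and B here. Which mice they are, and whether they are among the labelled 30 °C mice, is not known.

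The table holds 38924 genes. Gene names, positions (1-based) and exon lengths came from the GENCODE annotation of GRCm38, which matched 96.6% of the identifiers. In the deposited file 27 gene symbols had been turned into dates, and these were restored from the identifiers. Of the 13 mitochondrially encoded messenger RNAs, mt-Co2, mt-Atp8, mt-Atp6, mt-Co3 and mt-Nd4l held between 0 and 12 counts over the 12 libraries, and 8 were tested. Total counts ranged from 18290162 to 32513051 per library, except 86438386 in 22 °C mouse 3. The library code of that mouse (8846) also lies apart from those of the other libraries (7509 to 7520). At the smallest total, 1 CPM corresponds to about 18.3 counts before the TMM scaling described below, whose factor for that library was 0.917. Pairs of libraries of 1 temperature differed by far more than counting noise (chi-square per degree of freedom of at least 22.8), so no library was counted as a copy of another.

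Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed by filterByExpr with the temperatures as groups, which left 14870 genes, and library sizes were scaled by TMM. A model with 1 factor of 3 temperatures was fitted to all 12 libraries by glmQLFit with robust estimation, so that the groups share 1 estimate of the spread. Contrasts were tested two-sided with glmQLFTest (edgeR's quasi-likelihood test): 6 °C against 30 °C, 22 °C against 30 °C, 6 °C against 22 °C, any temperature, and the difference of the steps. The last is the log2 fold change from 22 to 6 °C minus that from 30 to 22 °C. P-values were adjusted by Benjamini-Hochberg over all tested genes. A gene is said to have changed at an adjusted p under 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic. CPM values are edgeR's TMM-normalised CPM with their SD over 4 mice. Adjusted p-values weigh a difference against the spread between mice, estimated over all 3 groups together, and speak only for the mice of these groups.

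The 35 gene lists for fuel metabolism, signalling, stress and cell types were tested with camera (limma 3.58.1) with a preset correlation between genes of 0.01, adjusted over the lists of a comparison, for lists with at least 5 tested members. The same test with a correlation estimated per list, and fry, were run as alternatives. Called members were counted after adjustment over all genes and adjusted over the list alone. Of the 684 genes listed, 28 stand in more than 1 list. The lists, the designs, the alternatives and the rule for naming genes were fixed before the data were examined. The rule takes, from genes with a mean of at least 5 CPM, an adjusted p under 0.05 and no overlap of the ranges of the groups, the 10 largest changes in each direction at 6 °C against 30 °C and the 6 largest in each direction for the other pairs. It adds the 4 smallest p-values in each direction for the difference of the steps (without the condition on ranges), the 3 members with the smallest p of each called list, 1 member of each other list, and a panel of 24 genes of thermogenesis and lipogenesis. Clone and predicted names were left out. It named 185 genes, of which the text gives those that illustrate each group. Results of genes withheld for evaluation were left out of the text.

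Alternatives were RLE, upper-quartile and total-count scaling, scaling without mitochondrial genes and Ucp1, no filter or a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, limma voom, glmQLFit without robust estimation, the mouse number as a block (the 10 matched libraries), leaving out each library, the skeletal muscle marker level as a covariate, only the 8 libraries compared, a 2-fold threshold, glmTreat against 1.5-fold, and an adjusted p under 0.01. Thinning the deep library, leaving out pairs of libraries (among them 30 °C mice A and B), and removing a per-library trend in exon length and GC content (99.2% of tested genes had both values) were added after the data were seen. The procedure was tested on simulated data drawn from each gene's mean over all libraries, its dispersion and the real library sizes, with 50 genes changed at each of 4 sizes. For 6 °C against 30 °C, over 14710 genes, 28% of genes changed by 0.5 on the log2 scale were recovered, 70% of those changed by 1, 90% by 2 and 98% by 4. There were 3 false calls among 146. For 22 °C against 30 °C, over 14722 genes, the shares were 18%, 70%, 86% and 100%, with 8 false calls among 145. For 6 °C against 22 °C, over 14721 genes, they were 28%, 78%, 90% and 98%, with 7 false calls among 154. Far fewer genes were changed in these simulations than were called in the data, as many up as down. The rates therefore need not hold for the data. In a further simulation of 6 °C against 30 °C camera called the 1 list that had been shifted by 1 (adjusted p = 9.1e-37) and 0 others. Its genes were drawn independently, so it cannot show how camera behaves where the members of a list move together. Figures were drawn with matplotlib 3.10.9.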

Results

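Transcripts were measured by RNA sequencing of total RNA from the interscapular brown fat of 12 wild-type C57BL/6J mice. Brown fat is a tissue that burns fuel to make heat, and its interscapular depot lies between the shoulder blades. The mice lived at 1 of 3 ambient temperatures from 10 to 14 weeks of age, 4 mice at each: 30 °C, which is thermoneutral for a mouse, 22 °C, which is mild cold, and 6 °C, which is severe cold. The comparisons ask how 4 weeks at each temperature changed the transcripts of the depot, and whether the step from 22 °C to 6 °C repeated the step from 30 °C to 22 °C. Library totals were 26250748, 22529457, 29870740 and 25881450 counts at 30 °C (mice 1, 2, A and B), 21214299, 18290162, 86438386 and 23630800 at 22 °C (mice 1 to 4), and 25973000, 31832748, 32513051 and 20868184 at 6 °C (mice 1 to 4). Genes encoded by the mitochondrial genome took 24.2% ± 1.92 (SD, n = 4) of the counts at 30 °C, 20.8% ± 1.09 at 22 °C and 19.1% ± 1.61 at 6 °C. Within a temperature, the Spearman correlation of the counts of any pair of libraries was at least 0.975.

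**Figure D1:**
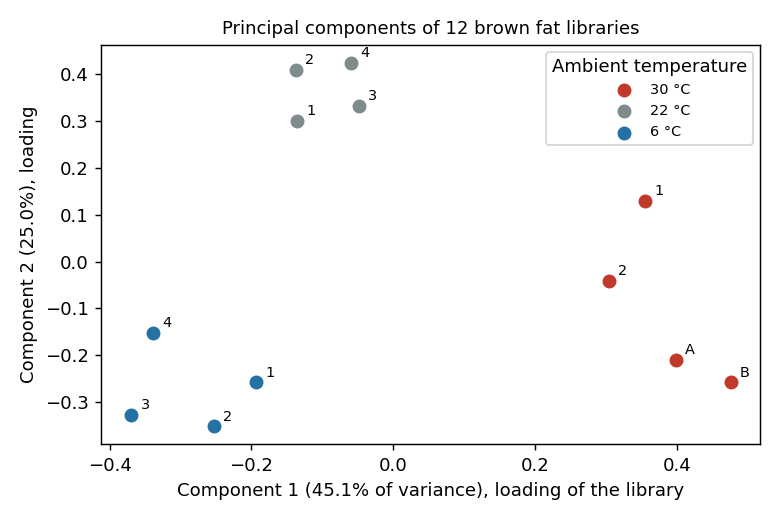
Loadings of the 12 brown fat libraries on the first and second principal components of log2 CPM over 14870 tested genes (axes carry no unit, points are libraries coloured by temperature and marked with the mouse). The first component holds 45.1% of the variance, and the libraries of the 3 temperatures lie in separate groups.

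At 6 °C, brown fat held far more messenger RNA of its heat-producing and fatty acid-making genes than at 30 °C. Elovl3, an elongase of very long chain fatty acids that marks active brown fat, rose from 2.33 ± 0.973 CPM (SD, n = 4) to 735 ± 109, a 319-fold change, with log2 fold change 8.32, SE 0.40, adjusted p = 7.9e-08 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Ucp1, the uncoupling protein that turns the proton gradient into heat, rose 7.1-fold, from 1469 ± 569 to 10439 ± 1044 CPM (log2 fold change 2.83, SE 0.32, adjusted p = 2.0e-05). Fasn, fatty acid synthase, rose 20.5-fold, from 1783 ± 1585 to 36611 ± 4942 CPM (log2 fold change 4.36, SE 0.53, adjusted p = 4.5e-05). Bmp8b, a secreted factor of thermogenic brown fat, went from 0.202 ± 0.159 to 38.6 ± 23 CPM (log2 fold change 7.55, SE 0.73, adjusted p = 1.2e-05). Without 30 °C mouse 1 the log2 fold change of Fasn was 5.19 and that of Bmp8b 8.26. In the GRCm38 build Elovl3 lies on chromosome 19 from 46131897 to 46135694, Ucp1 on chromosome 8 from 83290352 to 83298452, Fasn on chromosome 11 from 120805846 to 120824547 and Bmp8b on chromosome 4 from 123105165 to 123132099, all annotated as protein-coding genes.

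The thermogenic programme and the routes of fuel supply rose together between 30 °C and 6 °C. In the thermogenic programme 19 of 26 genes rose and 1 fell (the same adjusted over the list alone, camera adjusted p = 1.7e-07, adjusted p = 0.282 with an estimated correlation). Dio2, which activates thyroid hormone within the cell, rose by 2.87 on the log2 scale (SE 0.52), Ppargc1a, a coactivator of mitochondrial genes, by 1.19 (SE 0.23), and Gk, glycerol kinase, by 2.83 (SE 0.28), while Cidea did not pass (0.25, adjusted p = 0.0911). In de novo lipogenesis 16 of 20 genes rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 6.8e-07, adjusted p = 0.313 with an estimated correlation). Acly, Acaca, Scd1 and Elovl6, which carry citrate carbon to long monounsaturated fatty acids, rose by 3.61, 3.10, 3.13 and 4.11, and the desaturase Fads1 fell by 1.39. Without 30 °C mouse 1, Acly rose by 4.20 and Acaca by 3.70. Of its regulators, Mlxipl, which encodes the glucose-sensing factor ChREBP, rose by 1.11 (adjusted p = 9.4e-04), while Srebf1 did not pass (0.35, adjusted p = 0.111). In the pentose phosphate pathway and NADPH supply 8 of 10 genes rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 3.3e-04, adjusted p = 0.313 with an estimated correlation). Pgd stood at 3.03 and G6pdx at 1.89. In triglyceride synthesis and the lipid droplet 16 of 22 genes rose and 3 fell (the same adjusted over the list alone, camera adjusted p = 7.8e-06, adjusted p = 0.282 with an estimated correlation). Agpat2 rose by 2.85, the droplet coat gene Plin2 by 2.32, while Dgat2 fell by 0.61.

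**Figure D2:**
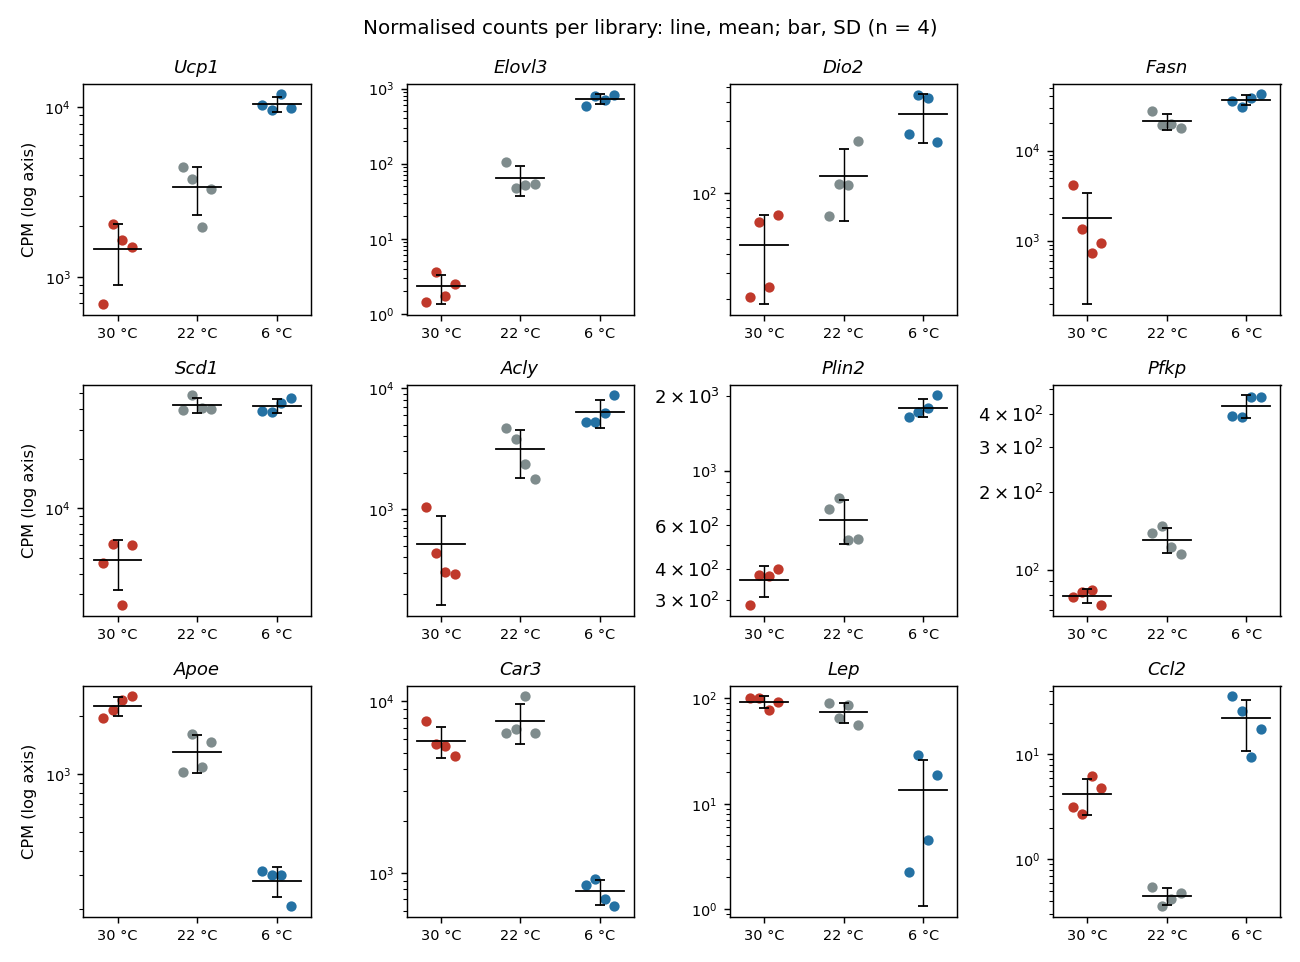
Normalised counts (CPM, log axis) of 12 genes in each library at 30, 22 and 6 °C; points are libraries, lines means and bars SDs (n = 4). Scd1 had a mean of 42385 CPM at 22 °C and 42109 at 6 °C, Car3 had 778 at 6 °C, and Ccl2 was lowest at 22 °C (0.453 CPM).

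Genes that burn fatty acids and glucose were higher at 6 °C than at 30 °C as well. In lipolysis and lipid uptake 12 of 21 genes rose and 2 fell (13 and 2 adjusted over the list alone, camera adjusted p = 0.00749, adjusted p = 0.313 with an estimated correlation). Mgll, which releases glycerol from the last fatty acid, rose by 1.70, and Angptl4, an inhibitor of lipoprotein lipase, fell by 2.11. In mitochondrial fatty acid oxidation 16 of 20 genes rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 6.8e-07, adjusted p = 0.336 with an estimated correlation). Acsl5, which activates long-chain fatty acids, rose by 4.10 and Cpt2 by 1.71. In peroxisomal oxidation 15 of 19 genes rose and 1 fell (the same adjusted over the list alone, camera adjusted p = 3.0e-06, adjusted p = 0.174 with an estimated correlation). In glucose uptake and glycolysis 16 of 21 genes rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 2.3e-07, adjusted p = 0.282 with an estimated correlation). Pfkp rose by 2.44 (SE 0.10), Aldoa by 2.01 and the insulin-regulated transporter Slc2a4 by 0.76, while Slc2a1 did not pass (-0.07, adjusted p = 0.732). In pyruvate dehydrogenase and the TCA cycle 25 of 30 genes rose and 1 fell (27 and 1 adjusted over the list alone, camera adjusted p = 5.0e-09, adjusted p = 0.313 with an estimated correlation). Both subunits of the mitochondrial pyruvate carrier rose, Mpc1 by 2.03 and Mpc2 by 2.00. Of the exons of Mpc1, 23.1% lie under another gene on the other strand. The inhibitory kinase Pdk4 rose by 0.97, a call lost without 30 °C mice A and B (adjusted p = 0.0672). In the nuclear-encoded respiratory chain 40 of 62 genes rose and 2 fell (42 and 2 adjusted over the list alone, camera adjusted p = 6.8e-07, adjusted p = 0.553 with an estimated correlation). With total counts as the only scaling, 19 of these genes were higher and 13 lower.

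Members of the glycogen, sterol and signalling lists were called as well. In glycogen metabolism 12 of 21 genes rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 0.00188, adjusted p = 0.383 with an estimated correlation). The synthase gene Gys2 rose by 1.97. In cholesterol synthesis 17 of 22 genes rose and 0 fell (18 and 0 adjusted over the list alone, camera adjusted p = 1.7e-07, adjusted p = 0.313 with an estimated correlation). Nsdhl rose by 2.60. In insulin and mTOR signalling 15 of 27 genes rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 0.00188, adjusted p = 0.282 with an estimated correlation). Mtor rose by 1.98 and Akt2 by 0.41, and Akt1 stood at 0.02 (SE 0.12, adjusted p = 0.869). With total counts as the only scaling the call of Akt2 was lost and Akt1 fell by 0.29 (adjusted p = 0.0485), and the median of the insulin list turned to -0.06. In thyroid hormone and nuclear receptor genes 8 of 18 genes rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 0.0198, adjusted p = 0.313 with an estimated correlation). The median of that list turned to -0.14 with total counts only. In beta-adrenergic and cAMP signalling 10 of 26 genes rose and 6 fell (the same adjusted over the list alone, camera adjusted p = 0.143, adjusted p = 0.553 with an estimated correlation). Adcy3, an adenylyl cyclase gene with 22.1% of its exons under another gene on the other strand, rose by 2.82, and with total counts only 4 members of this list were higher and 10 lower. In creatine and calcium cycling 3 of 11 genes rose and 4 fell (the same adjusted over the list alone, camera adjusted p = 0.695, adjusted p = 0.834 with an estimated correlation). This list holds muscle genes. Alpl rose by 2.01. Of the 8 mitochondrially encoded messenger RNAs tested, 1 was higher and 3 lower, the same adjusted over the list alone (camera adjusted p = 0.735, adjusted p = 0.914 with an estimated correlation).

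Other genes fell in the cold, among them those of the matrix, the vessels and T and natural killer cells. Nnat, neuronatin, fell 30.7-fold from 160.1 ± 49.1 to 5.19 ± 1.32 CPM (log2 fold change -4.94, SE 0.47, adjusted p = 1.1e-05), Tusc3 fell 11.5-fold (log2 fold change -3.52, SE 0.15, adjusted p = 1.5e-08), and Clu, clusterin, 9.63-fold (log2 fold change -3.27, SE 0.28, adjusted p = 3.9e-06). Apoe, which encodes a lipoprotein component, fell by 3.01, Lep, leptin, fell by 2.78 (adjusted p = 0.00448), and Car3, a carbonic anhydrase gene abundant in fat, fell by 2.92. Without 6 °C mouse 2, Lep fell by 3.48. In the extracellular matrix 1 of 24 genes rose and 19 fell (1 and 20 adjusted over the list alone, camera adjusted p = 6.0e-05, adjusted p = 0.503 with an estimated correlation). Mmp2 fell by 2.06 and the collagen VI gene Col6a1 fell by 1.31, while Loxl1, a cross-linking enzyme gene, rose by 1.63. In fibroblasts and preadipocytes 0 of 15 genes rose and 11 fell (0 and 12 adjusted over the list alone, camera adjusted p = 2.3e-04, adjusted p = 0.383 with an estimated correlation). The matrix proteoglycan genes Dcn and Lum stood at -1.80 and -1.89. In endothelial markers 1 of 15 genes rose and 10 fell (the same adjusted over the list alone, camera adjusted p = 0.00601, adjusted p = 0.365 with an estimated correlation). Tie1 stood at -1.15 and Cdh5 at -0.70. In pericytes and smooth muscle 1 of 12 genes rose and 7 fell (the same adjusted over the list alone, camera adjusted p = 0.19, adjusted p = 0.657 with an estimated correlation). In T and natural killer cells 0 of 13 genes rose and 13 fell (the same adjusted over the list alone, camera adjusted p = 6.0e-05, adjusted p = 0.313 with an estimated correlation). Lck stood at -2.68 and Cd4 at -2.21. These markers were scarce, with a mean log2 CPM of 0.07 to 0.98 at 30 °C and -2.29 to -1.17 at 6 °C. In macrophages 0 of 18 genes rose and 12 fell (1 and 12 adjusted over the list alone, camera adjusted p = 0.0111, adjusted p = 0.571 with an estimated correlation). C1qa stood at -1.70 and Itgax at -1.63. The 30 °C libraries were uneven here, with a mean log2 CPM of the macrophage markers of 4.21 and 4.19 in mice 1 and 2 and of 5.43 and 5.53 in mice A and B. Without mice A and B, 1 macrophage gene was higher and 8 were lower at 6 °C, and the list was not called (camera adjusted p = 0.0934).

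Proliferation genes were also lower at 6 °C than at 30 °C. For the proliferation list 1 of 25 genes rose and 20 fell (the same adjusted over the list alone, camera adjusted p = 0.00171, adjusted p = 0.553 with an estimated correlation). Without 30 °C mice A and B, 0 of its genes were higher and 5 lower (camera adjusted p = 0.0428). For the interferon response 0 of 21 genes rose and 4 fell (0 and 2 adjusted over the list alone, camera adjusted p = 0.474, adjusted p = 0.914 with an estimated correlation). The median of the interferon list was -0.06. Among secreted factors of brown fat 7 of 24 genes rose and 10 fell (the same adjusted over the list alone, camera adjusted p = 0.666, adjusted p = 0.776 with an estimated correlation). Fgf21 rose by 3.03 from a mean of 0.176 CPM and Nrg4 by 0.45, a call lost with total counts only and without 30 °C mice A and B (adjusted p = 0.0508). Among white adipocyte markers 2 of 11 genes rose and 5 fell (the same adjusted over the list alone, camera adjusted p = 0.432, adjusted p = 0.776 with an estimated correlation). For the unfolded protein and integrated stress response 8 of 25 genes rose and 4 fell (the same adjusted over the list alone, camera adjusted p = 0.222, adjusted p = 0.365 with an estimated correlation). Atf5 rose by 1.68. With total counts only, 5 of its members were higher and 7 lower. For B cells 0 of 8 genes rose and 4 fell (the same adjusted over the list alone, camera adjusted p = 0.0941, adjusted p = 0.525 with an estimated correlation). That list was called without 6 °C mouse 3 (camera adjusted p = 0.0409). For neutrophils and mast cells 2 of 8 genes rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 0.886, adjusted p = 0.937 with an estimated correlation). Their median of -0.31 and the upward test differed in sign. For skeletal muscle, whose RNA can enter with the depot, 0 of 20 genes passed (the same adjusted over the list alone, camera adjusted p = 0.0664, adjusted p = 0.776 with an estimated correlation). The list was called without 6 °C mouse 1 (camera adjusted p = 0.00797), 6 °C mouse 4 (0.0126) or 30 °C mice A and B (0.0392). The mean log2 CPM of its markers ranged from -0.65 to 6.04 within the 6 °C group. For Schwann cells and nerves 2 of 11 genes rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 0.735, adjusted p = 0.914 with an estimated correlation).

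In all, 8444 of 14870 tested genes changed between 30 °C and 6 °C, 3767 higher and 4677 lower at 6 °C, of which 871 were at least 2-fold higher and 1845 at least 2-fold lower. Scaling by total counts alone gave 1939 higher and 7888 lower and moved the median of all genes by -0.32 on the log2 scale, and removing a trend in exon length and GC content gave 4746 higher and 3496 lower with a shift of 0.13. Each of the 20 list calls in this comparison was lost with an estimated correlation. The counts of members above describe the lists and do not test them, and 56.8% of all tested genes changed.

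Lipogenic and thermogenic genes rose from 30 °C to 22 °C, and genes of macrophages fell to low levels. Elovl3 rose 28.1-fold to 64.9 ± 27.2 CPM (log2 fold change 4.81, SE 0.35, adjusted p = 7.5e-06; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Fasn 11.8-fold to 21111 ± 4430.4 CPM (log2 fold change 3.57, SE 0.51, adjusted p = 2.8e-04), Scd1 8.82-fold (SE 0.23 on the log2 scale, adjusted p = 3.2e-06) and Ucp1 2.3-fold to 3373 ± 1053 CPM (log2 fold change 1.20, SE 0.30, adjusted p = 0.00712). The call of Ucp1 was lost without 30 °C mice A and B (1.29, adjusted p = 0.0611), and without 30 °C mouse 1 the log2 fold change of Fasn was 4.40. Mmp12, a macrophage elastase gene on chromosome 9 from 7344381 to 7369499, fell 79.5-fold from 19.9 ± 8.04 to 0.236 ± 0.0942 CPM (log2 fold change -6.31, SE 0.42, adjusted p = 3.2e-06). Trem2, a lipid receptor of macrophages, fell 36.9-fold (log2 fold change -5.21, SE 0.93, adjusted p = 0.00131). Spp1, osteopontin, changed by -5.56 (SE 1.20, adjusted p = 0.00414), a call that limma voom did not make. At 30 °C Trem2 stood at 3.69 and 7.44 CPM in mice 1 and 2 and at 42.9 and 37.4 in mice A and B, and Spp1 at 2.10, 5.11, 59.3 and 43.7. Without mice A and B, Trem2 fell 8.79-fold (adjusted p = 0.00368) and Spp1 fell by 2.61 (adjusted p = 0.0269). Without mouse A alone Spp1 fell by 4.86, and without 22 °C mouse 1 Trem2 fell by 5.80. Dio2 stood at 1.52 (SE 0.50, adjusted p = 0.0302) and did not pass without 30 °C mouse 1 (adjusted p = 0.063), 30 °C mouse A (adjusted p = 0.0715) or 22 °C mouse 4 (adjusted p = 0.0873), nor without 30 °C mice A and B together (adjusted p = 0.0977).

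Most lists of fuel use were called at this first step, and lipolysis and lipid uptake was not: there 10 of 21 genes rose and 4 fell (the same adjusted over the list alone, camera adjusted p = 0.0635, adjusted p = 0.312 with an estimated correlation). It was called without 30 °C mouse 2 (camera adjusted p = 0.0475), 22 °C mouse 2 (0.0375) or 30 °C mice A and B (0.0448). In the thermogenic programme 14 of 26 genes rose and 0 fell (the same adjusted over the list alone, camera adjusted p = 4.3e-05, adjusted p = 0.298 with an estimated correlation). In de novo lipogenesis 16 of 20 genes rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 4.6e-07, adjusted p = 0.298 with an estimated correlation). Acly stood at 2.60, Elovl6 at 3.02, Mlxipl at 0.79 (adjusted p = 0.00984) and Srebf1 at 0.94. The call of Mlxipl was lost without 30 °C mice A and B (0.60, adjusted p = 0.123), and Acly stood at 3.19 without 30 °C mouse 1. In the pentose phosphate pathway 7 of 10 genes rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 1.6e-04, adjusted p = 0.298 with an estimated correlation). In triglyceride synthesis and the lipid droplet 16 of 22 genes rose and 0 fell (17 and 0 adjusted over the list alone, camera adjusted p = 2.3e-05, adjusted p = 0.298 with an estimated correlation). In mitochondrial fatty acid oxidation 16 of 20 genes rose and 0 fell (18 and 0 adjusted over the list alone, camera adjusted p = 4.2e-09, adjusted p = 0.298 with an estimated correlation). In peroxisomal oxidation 13 of 19 genes rose and 0 fell (the same adjusted over the list alone, camera adjusted p = 8.2e-07, adjusted p = 0.128 with an estimated correlation). In glycolysis 14 of 21 genes rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 9.4e-04, adjusted p = 0.31 with an estimated correlation). Slc2a1 fell by 0.52 (adjusted p = 0.0215), a call lost without 30 °C mouse 2 (adjusted p = 0.0727), 30 °C mouse B (0.0618), 22 °C mouse 1 (0.0574) or 22 °C mouse 2 (0.0571), or without 30 °C mice A and B (0.0858). In pyruvate dehydrogenase and the TCA cycle 27 of 30 genes rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 3.2e-09, adjusted p = 0.31 with an estimated correlation).

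Genes of the respiratory chain rose as well. Among its nuclear genes 58 of 62 genes rose and 0 fell (58 and 1 adjusted over the list alone, camera adjusted p = 2.1e-18, adjusted p = 0.31 with an estimated correlation). Cox6a1 rose by 1.14, Uqcrq by 1.09 and Sdha by 0.78. Of the 8 mitochondrially encoded messenger RNAs tested, 0 were higher and 1 lower at 22 °C, the same adjusted over the list alone (camera adjusted p = 0.792, adjusted p = 0.947 with an estimated correlation). In glycogen metabolism 12 of 21 genes rose and 1 fell (the same adjusted over the list alone, camera adjusted p = 0.00183, adjusted p = 0.332 with an estimated correlation). In cholesterol synthesis 13 of 22 genes rose and 1 fell (15 and 1 adjusted over the list alone, camera adjusted p = 1.4e-04, adjusted p = 0.355 with an estimated correlation). Insig1 rose by 2.07. In insulin and mTOR signalling 13 of 27 genes rose and 2 fell (14 and 2 adjusted over the list alone, camera adjusted p = 0.00228, adjusted p = 0.298 with an estimated correlation). Akt2 stood at 0.42 and Akt1 at -0.13 (adjusted p = 0.394). With total counts only, the call of Akt2 was lost and Akt1 passed at -0.39. In thyroid hormone and nuclear receptor genes 6 of 18 genes rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.0412, adjusted p = 0.298 with an estimated correlation). Its median turned to -0.03 with total counts only, and the list was not called without 30 °C mouse B (camera adjusted p = 0.0654), 22 °C mouse 3 (0.0553), 22 °C mouse 4 (0.0587) or 30 °C mice A and B together (0.0885). The beta-adrenergic list was not called (camera adjusted p = 0.865), and its median of -0.07 and its upward test differed in sign. The same held for the secreted factors, with a median of -0.02 and an upward test (camera adjusted p = 0.893), and for neutrophils and mast cells, with a median of 0.04 and a downward test (camera adjusted p = 0.865).

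Genes of dividing cells, of macrophages, T and natural killer cells and of matrix were lower at 22 °C than at 30 °C. In proliferation 0 of 25 genes rose and 24 fell (the same adjusted over the list alone, camera adjusted p = 2.5e-11, adjusted p = 0.298 with an estimated correlation). Top2a stood at -3.10 and Ccna2 at -2.92. In the interferon response 0 of 21 genes rose and 18 fell (the same adjusted over the list alone, camera adjusted p = 6.0e-06, adjusted p = 0.355 with an estimated correlation). Mx1 stood at -3.18 and Ifit1 at -1.65. In macrophages 0 of 18 genes rose and 15 fell (the same adjusted over the list alone, camera adjusted p = 5.7e-06, adjusted p = 0.31 with an estimated correlation). In T and natural killer cells 0 of 13 genes rose and 13 fell (the same adjusted over the list alone, camera adjusted p = 3.1e-06, adjusted p = 0.298 with an estimated correlation). In B cells 0 of 8 genes rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 0.0566, adjusted p = 0.355 with an estimated correlation). The B cell list was called without 22 °C mouse 2 (camera adjusted p = 0.0445), 6 °C mouse 3 (0.0482) or 30 °C mice A and B together (0.038). In the extracellular matrix 0 of 24 genes rose and 22 fell (the same adjusted over the list alone, camera adjusted p = 3.7e-08, adjusted p = 0.31 with an estimated correlation). In fibroblasts and preadipocytes 0 of 15 genes rose and 11 fell (0 and 13 adjusted over the list alone, camera adjusted p = 1.9e-04, adjusted p = 0.332 with an estimated correlation). Among endothelial markers 0 of 15 genes rose and 12 fell (the same adjusted over the list alone, camera adjusted p = 1.2e-05, adjusted p = 0.298 with an estimated correlation).

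In all, 6634 of 14870 genes changed between 30 °C and 22 °C, 3248 higher and 3386 lower at 22 °C, with 421 at least 2-fold higher and 1449 at least 2-fold lower. Scaling by total counts alone gave 1419 higher and 6224 lower with a shift of the median gene of -0.26, and removing the trend in exon length and GC content gave 4611 higher and 2621 lower with a shift of 0.14.

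**Figure D3:**
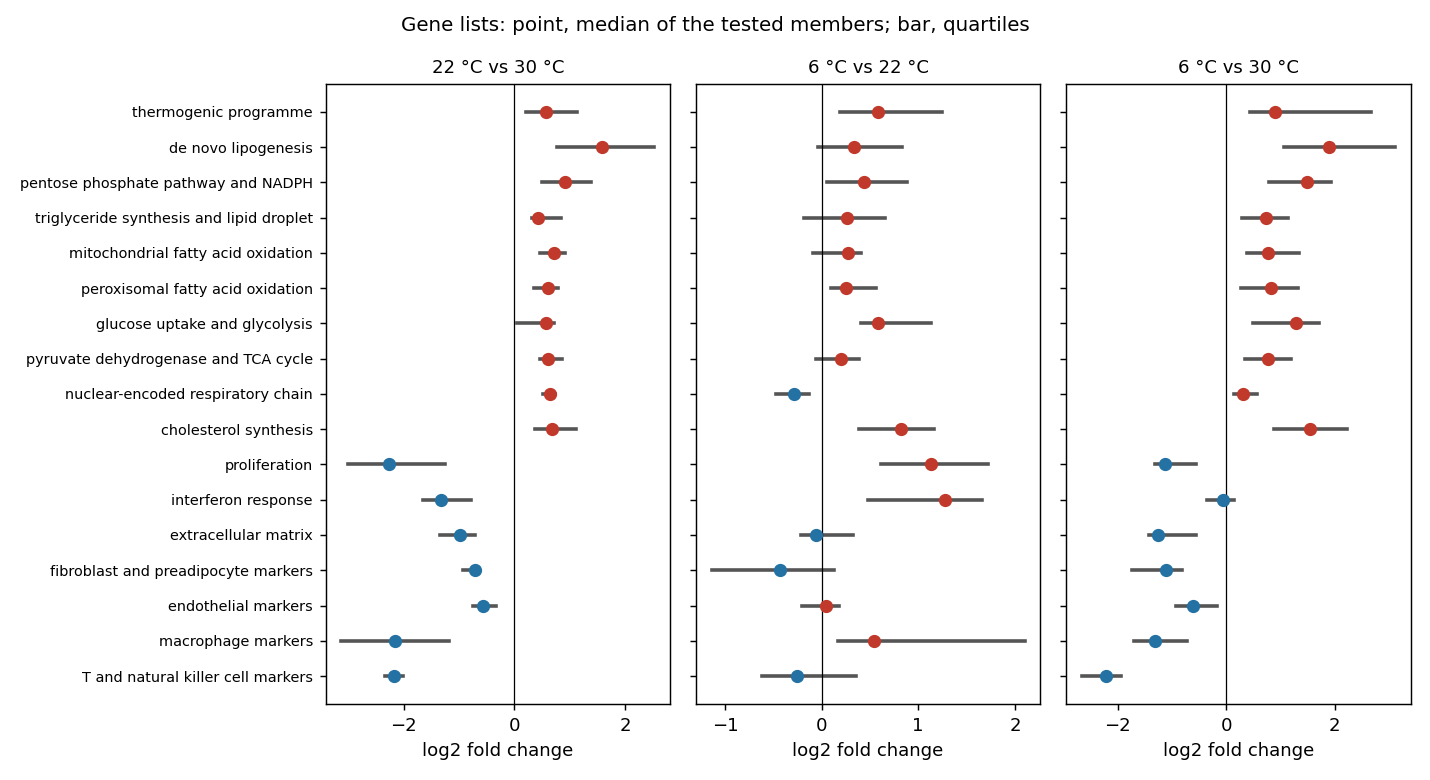
Log2 fold changes of 17 gene lists over the step from 30 °C to 22 °C, the step from 22 °C to 6 °C, and both together; points are medians over the tested members (red above 0, blue below), bars their quartiles. The respiratory chain median was 0.65 over the first step and -0.29 over the second, and the proliferation median was -2.27 and then 1.13.

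From 22 °C to 6 °C, the chemokine genes Ccl2 and Ccl7 and several macrophage genes rose from their low level, thermogenic genes rose further, and Car3, Hcar1 and Lep fell. Ccl2, a monocyte chemoattractant gene on chromosome 11 from 82035571 to 82037453, rose 48.6-fold from 0.453 ± 0.0799 to 22 ± 11.2 CPM (log2 fold change 5.60, SE 0.47, adjusted p = 1.6e-05; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Ccl7, another monocyte chemoattractant gene, rose by 5.19, Slfn4, an interferon-inducible gene of myeloid cells, by 6.43 and Mmp12 by 4.92. Bmp8b rose 52.8-fold (log2 fold change 5.72, SE 0.63, adjusted p = 1.2e-04), Elovl3 11.3-fold (log2 fold change 3.50, SE 0.31, adjusted p = 2.7e-05) and Ucp1 3.1-fold (log2 fold change 1.63, SE 0.31, adjusted p = 0.00213). Without 22 °C mouse 3 the log2 fold change of Bmp8b was 6.78, and without 6 °C mouse 1 that of Slfn4 was 5.73. Car3, on chromosome 3 from 14863512 to 14872523, fell 9.85-fold from 7658 ± 1997 to 778 ± 129 CPM (log2 fold change -3.30, SE 0.21, adjusted p = 1.7e-06), and Hcar1, the lactate receptor gene, fell by 2.89. Over the same step Anxa8 fell by 3.48, Mycl fell by 3.30 and Lep fell by 2.45. Without 6 °C mouse 2, Anxa8 fell by 4.09 and Lep fell by 3.16.

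Scd1 stood at -0.01 over this step (SE 0.21, adjusted p = 0.978), and Fasn at 0.79, Acly at 1.01 and Acaca at 0.58 did not pass (adjusted p = 0.208, 0.101 and 0.238). Without 30 °C mouse 1, which is outside this comparison but enters the shared estimate of the spread, these 3 passed at adjusted p = 0.00916, 0.0236 and 0.0109. Elovl6 rose by 1.10 (adjusted p = 0.0166). Dio2, at 1.36, did not pass (adjusted p = 0.0568) and passed without 30 °C mouse 1 (0.0421) or 22 °C mouse 4 (0.0317). Srebf1 fell by 0.58 (adjusted p = 0.0265), a call lost without 22 °C mouse 1 (0.0747), 22 °C mouse 2 (0.0682), 6 °C mouse 1 (0.0726) or 6 °C mouse 3 (0.0738). Cidea fell by 0.33 (adjusted p = 0.0471), a call lost without any of 9 libraries (30 °C mice 1, 2 and A, 22 °C mice 2 and 4, and each of the 6 °C mice), where the adjusted p ranged from 0.0532 to 0.148. Slc2a1, at 0.45, did not pass (adjusted p = 0.0526) and passed without 30 °C mouse 1 (0.0377), 30 °C mouse 2 (0.0453) or 6 °C mouse 2 (0.0355), and Nrg4, at -0.25 (adjusted p = 0.144), passed without 22 °C mouse 1 (0.0252).

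Genes of glucose use, sterol synthesis and heat production rose further at this step, and those of the respiratory chain fell. In glucose uptake and glycolysis 14 of 21 genes rose and 0 fell (15 and 1 adjusted over the list alone, camera adjusted p = 2.1e-07, adjusted p = 0.443 with an estimated correlation). Pfkp stood at 1.72, Hk1 at 1.61 and Gpi1 at 1.13. In the thermogenic programme 14 of 26 genes rose and 3 fell (15 and 3 adjusted over the list alone, camera adjusted p = 1.0e-04, adjusted p = 0.767 with an estimated correlation). In cholesterol synthesis 14 of 22 genes rose and 2 fell (15 and 2 adjusted over the list alone, camera adjusted p = 7.6e-05, adjusted p = 0.876 with an estimated correlation). In triglyceride synthesis and the lipid droplet 10 of 22 genes rose and 2 fell (10 and 3 adjusted over the list alone, camera adjusted p = 0.0237, adjusted p = 0.876 with an estimated correlation). Plin2 rose by 1.51. The call of that list was lost without 22 °C mouse 3 (camera adjusted p = 0.0642). In peroxisomal oxidation 10 of 19 genes rose and 2 fell (10 and 3 adjusted over the list alone, camera adjusted p = 0.0237, adjusted p = 0.767 with an estimated correlation). In pyruvate dehydrogenase and the TCA cycle 11 of 30 genes rose and 1 fell (the same adjusted over the list alone, camera adjusted p = 0.0343, adjusted p = 0.876 with an estimated correlation), a call lost without 22 °C mouse 3 (camera adjusted p = 0.162) or 6 °C mouse 3 (0.11). De novo lipogenesis was not called: 4 of 20 genes rose and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.117, adjusted p = 0.876 with an estimated correlation). It was called without 30 °C mouse 1 (camera adjusted p = 0.0379) or 22 °C mouse 1 (0.0444). In the nuclear-encoded respiratory chain 0 of 62 genes rose and 30 fell (0 and 34 adjusted over the list alone, camera adjusted p = 7.6e-06, adjusted p = 0.876 with an estimated correlation). Cox6c fell by 0.69 and Ndufb3 fell by 0.71.

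Cell cycle and interferon genes rose from their 22 °C level. In proliferation 19 of 25 genes rose and 0 fell (21 and 0 adjusted over the list alone, camera adjusted p = 2.1e-07, adjusted p = 0.876 with an estimated correlation). In the interferon response 14 of 21 genes rose and 0 fell (15 and 0 adjusted over the list alone, camera adjusted p = 1.3e-04, adjusted p = 0.876 with an estimated correlation). The 6 °C libraries were uneven: their list scores (mean log2 CPM) were 4.63 and 4.35 in mice 1 and 2 and 3.39 and 3.47 in mice 3 and 4, against 2.89 to 3.13 at 22 °C. Mx1 rose by 3.51, and by 2.84 without 6 °C mouse 1. In macrophages 7 of 18 genes rose and 2 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.0307, adjusted p = 0.876 with an estimated correlation). The macrophage call was lost without 22 °C mouse 2 (camera adjusted p = 0.0663) or 6 °C mouse 2 (0.0668). Trem2 and Gpnmb rose by 3.31 and 3.46, and C1qa stood at -0.13 (adjusted p = 0.677). In the unfolded protein and integrated stress response 11 of 25 genes rose and 3 fell (the same adjusted over the list alone, camera adjusted p = 0.0177, adjusted p = 0.351 with an estimated correlation). Fgf21 rose by 3.54 and Mthfd2 by 1.39. For skeletal muscle markers 0 of 20 genes passed (the same adjusted over the list alone, camera adjusted p = 0.0309, adjusted p = 0.882 with an estimated correlation), a list call lost without 22 °C mouse 4 (camera adjusted p = 0.11) or 6 °C mouse 3 (0.34). For T and natural killer cells 0 of 13 genes passed (the same adjusted over the list alone, camera adjusted p = 0.697, adjusted p = 0.921 with an estimated correlation). The median and the test differed in sign for creatine and calcium cycling (median -0.49, test upward), the extracellular matrix (-0.06, upward) and B cells (0.04, downward). The secreted factors had a median of -0.20, a mean of 0.12 and a downward test.

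In all, 5091 of 14870 genes changed between 22 °C and 6 °C, 2511 higher and 2580 lower at 6 °C, with 720 at least 2-fold higher and 606 at least 2-fold lower. Scaling by total counts alone gave 1996 higher and 3088 lower with a shift of the median gene of -0.06.

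Over the 3 temperatures, 9770 of 14870 genes changed somewhere, and for 4353 the step from 22 °C to 6 °C differed from the step from 30 °C to 22 °C. Counting calls over both steps, 790 genes rose at each and 440 fell at each, 609 rose and then fell, and 763 fell and then rose. Ccnd1, cyclin D1, is an example of the last kind: it stood at 33.6 ± 4.39, 8.88 ± 1.59 and 37.6 ± 4.59 CPM at 30, 22 and 6 °C (difference of the steps 4.02, SE 0.25, adjusted p = 4.5e-06; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Ccnd1 lies on chromosome 7 from 144929931 to 144939925, and 23.4% of its exons lie under another gene on the other strand. Slc43a2, an amino acid transporter gene, stood at 59.7 ± 13.4, 34.3 ± 3.09 and 138 ± 12.7 CPM (adjusted p = 8.3e-05). Fcor, a FoxO1 corepressor gene, showed the opposite shape, with 9.38 ± 0.644, 36.7 ± 0.936 and 21 ± 2 CPM (difference of the steps -2.77, SE 0.13, adjusted p = 3.3e-07), as did Gstz1 at 204 ± 26.6, 431 ± 36.2 and 208 ± 13.9 CPM (adjusted p = 2.3e-05). Swi5 (-1.62) and Acaa1a (-1.49) had the same shape as Fcor. How reads were assigned between Acaa1a and its paralog Acaa1b is not given in the sources used here.

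As groups, genes of proliferation, interferon response and macrophages were lowest at 22 °C, and those of the respiratory chain were highest there. For the difference of the steps in proliferation 22 of 25 genes were more positive at the colder step and 0 more negative (the same adjusted over the list alone, camera adjusted p = 6.5e-15, adjusted p = 0.559 with an estimated correlation). The median was 3.37. In the interferon response 17 of 21 genes were more positive at the colder step and 0 more negative (the same adjusted over the list alone, camera adjusted p = 1.1e-07, adjusted p = 0.559 with an estimated correlation). Its median was 2.55. In macrophages 15 of 18 genes were more positive at the colder step and 1 more negative (15 and 2 adjusted over the list alone, camera adjusted p = 4.2e-06, adjusted p = 0.559 with an estimated correlation), and the median was 2.49. In T and natural killer cells 7 of 13 genes were more positive at the colder step and 0 more negative (the same adjusted over the list alone, camera adjusted p = 4.1e-04, adjusted p = 0.559 with an estimated correlation). In the extracellular matrix 15 of 24 genes were more positive at the colder step and 0 more negative (18 and 0 adjusted over the list alone, camera adjusted p = 4.2e-06, adjusted p = 0.559 with an estimated correlation). In endothelial markers 8 of 15 genes were more positive at the colder step and 0 more negative (the same adjusted over the list alone, camera adjusted p = 2.9e-04, adjusted p = 0.559 with an estimated correlation). In the stress response 9 of 25 genes were more positive at the colder step and 1 more negative (9 and 2 adjusted over the list alone, camera adjusted p = 0.0108, adjusted p = 0.343 with an estimated correlation).

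In the nuclear-encoded respiratory chain 0 of 62 genes were more positive at the colder step and 56 more negative (0 and 58 adjusted over the list alone, camera adjusted p = 8.0e-20, adjusted p = 0.559 with an estimated correlation). The median was -0.88. In de novo lipogenesis 2 of 20 genes were more positive at the colder step and 11 more negative (the same adjusted over the list alone, camera adjusted p = 5.0e-04, adjusted p = 0.559 with an estimated correlation). Scd1 stood at -3.15. In mitochondrial fatty acid oxidation 0 of 20 genes were more positive at the colder step and 10 more negative (0 and 11 adjusted over the list alone, camera adjusted p = 6.4e-05, adjusted p = 0.559 with an estimated correlation). In peroxisomal oxidation 0 of 19 genes were more positive at the colder step and 6 more negative (the same adjusted over the list alone, camera adjusted p = 0.0271, adjusted p = 0.559 with an estimated correlation). That call was lost without 22 °C mouse 1 (camera adjusted p = 0.074) or 30 °C mice A and B (0.0532). In pyruvate dehydrogenase and the TCA cycle 2 of 30 genes were more positive at the colder step and 14 more negative (the same adjusted over the list alone, camera adjusted p = 2.9e-04, adjusted p = 0.727 with an estimated correlation). Median, mean and test differed in sign for the thermogenic programme (median -0.16, mean 0.15, test downward), cholesterol synthesis (0.05, 0.04, downward), the secreted factors (-0.49, 0.25, downward), neutrophils and mast cells (-0.06, 0.31, upward) and Schwann cells (0.06, -0.28, downward), none of them called. The median of the thermogenic programme turned to 0.05 and that of triglyceride synthesis to 0.14 with total counts only.

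**Figure D4:**
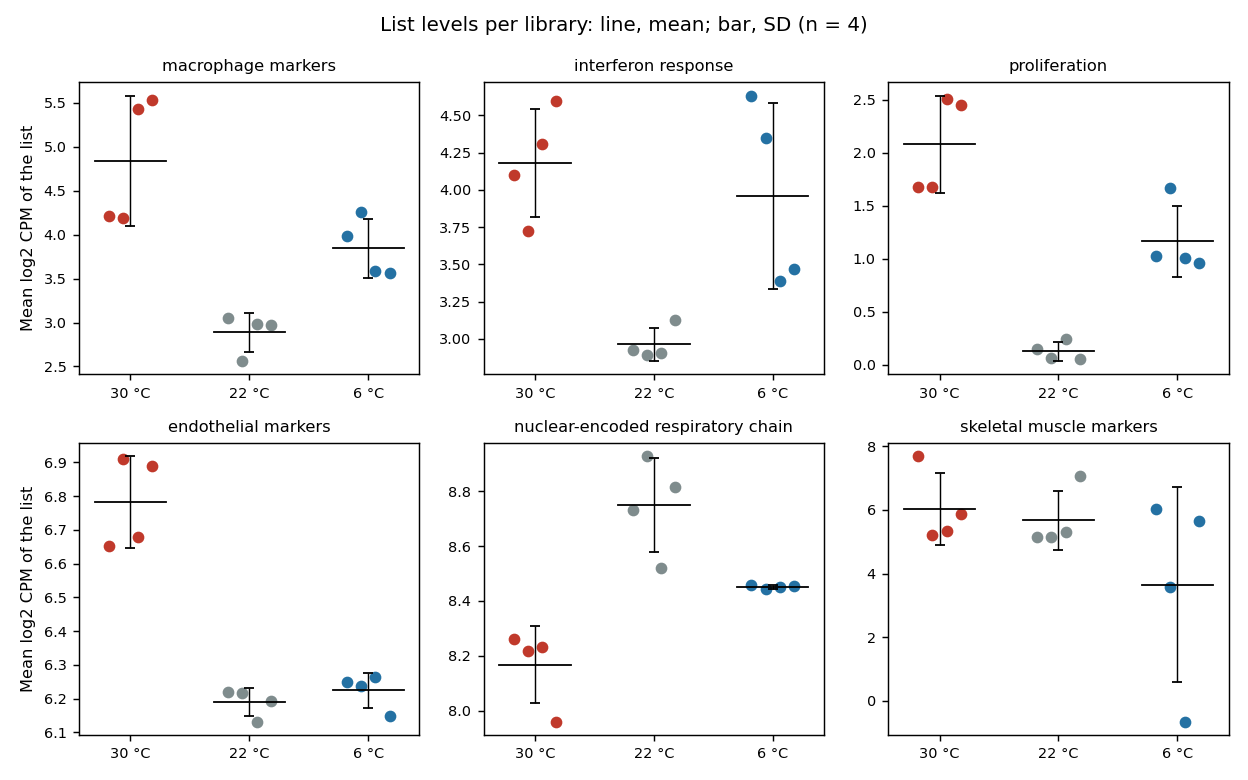
Mean log2 CPM of the members of 6 gene lists in each library at 30, 22 and 6 °C; points are libraries, lines means and bars SDs (n = 4). Macrophage, interferon and proliferation markers sit lowest at 22 °C and the respiratory chain highest there, while skeletal muscle markers range from -0.65 to 6.04 within the 6 °C group.

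Of the 4353 genes whose steps differed, 2126 had the more positive change at the colder step and 2227 at the warmer one. Scaling by total counts alone gave 3007 and 1275 and moved the median gene by 0.20, and removing the trend in exon length and GC content gave 1701 and 3008 with a shift of -0.15. For a change at any temperature, 4328 genes had their widest difference upwards in the cold and 5442 downwards, against 2354 and 8482 with total counts only.

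Many genes were called in the same direction at 22 °C and at 6 °C. Both comparisons with 30 °C called 2406 genes higher, 2496 lower and 140 in opposite directions, where independent lists of these sizes would share 823, 1065 and 1879. Elovl3, Fasn, Ucp1 and Acsl5 are among the genes higher in both, and Nnat, Tusc3 and Clu among those lower in both. Because the comparisons share the 30 °C libraries, 20 simulations drew all 12 libraries from the 30 °C means with no change between groups. They gave 0 shared calls and a covariance of log2 fold changes of 0.0335 against 0.479 observed. With no gene changed, hardly any call could arise. The 0 shared calls therefore cannot show how much overlap the shared libraries add where genes do change. The correlation across genes was 0.66 against 0.49 in those simulations, and genes are not independent replicates. With the 30 °C libraries divided so that each comparison had its own pair, 1681 to 1879 genes were higher in both, 1560 to 1939 lower and 45 to 208 opposite over 6 assignments, and the covariance ranged from 0.342 to 0.476.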

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

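The tests of the adipocyte share, of 30 °C mice A and B, of temperature as the source of the muscle signal and of the shape of the ribosomal protein genes were chosen after the results were seen, as were the settings with a library thinned, with mice A and B left out or with the exon length and GC trend removed. Dixon's test compares the gap between the most extreme library and its neighbour with the range of the 4, at its 95% critical value, and can mark a small difference (Fads1, 14.5 to 14.7 CPM in the other 3). By it, the lipid genes Elovl3 (105 CPM, 22 °C mouse 1), Elovl6 (188.7, 30 °C mouse 1, and 1151, 22 °C mouse 1), Scd1 (48686, 22 °C mouse 2), Fads1 (15.8, 6 °C mouse 2), Pgd (210.1, 30 °C mouse 1) and Car3 (10642, 22 °C mouse 3) stood above the other 3 of their group. So did Bmp8b (0.44, 30 °C mouse 1), Trem2 (1.44, 22 °C mouse 1), Ppargc1a (114, 6 °C mouse 3), Alpl (69.9, 6 °C mouse 2), Top2a (9.59, 6 °C mouse 2) and Cd4 (2.74, 30 °C mouse B). Below the others stood Mgll (1447, 6 °C mouse 1), Uqcrq (341, 30 °C mouse B), Ndufb3 (178, 30 °C mouse B), Cox6c (314, 30 °C mouse B), Gys2 (53.7, 22 °C mouse 4), Apoe (206, 6 °C mouse 4), Tie1 (139, 30 °C mouse 1) and Lck (0.417, 22 °C mouse 2).

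Among list scores (mean log2 CPM), libraries above their group by the same test were those for cholesterol synthesis (4.58, 30 °C mouse 2), creatine and calcium cycling (5.12, 22 °C mouse 4), insulin signalling (6.08, 22 °C mouse 3), proliferation (1.67, 6 °C mouse 2), interferon response (3.13, 22 °C mouse 4), extracellular matrix (7.53, 30 °C mouse B), neutrophils and mast cells (0.65, 22 °C mouse 3) and skeletal muscle (7.07, 22 °C mouse 4). The respiratory chain (7.96, 30 °C mouse B) and B cells (0.36, 30 °C mouse A) had a library below. Of the library measures, 22 °C mouse 3 stood apart in total counts (86438386) and genes detected (24407), 6 °C mouse 3 in the share of the 10 most abundant genes (27.8%) and 30 °C mouse B in its TMM factor (1.23). In all 35 of 399 groups examined were marked in this way, where chance marks about 1 in 20 groups (19.95 expected), and several genes of 1 library move together. The difference of the steps, 4353 genes, is listed here too because it tests whether groups respond unlike each other.

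Macrophage, interferon and proliferation genes were lowest at 22 °C. A lower share of adipocyte RNA at 6 °C would raise endothelial markers as much as macrophage markers. The median differences of the steps were 2.49 for macrophages and 0.60 for endothelial markers. The gap was 1.89 (spread 1.05, permutation p = 0.00176 over list membership), though genes of a list are not independent replicates. The difference of the steps also holds the step from 30 to 22 °C, where endothelial markers fell. Their score (mean log2 CPM) was 6.13 to 6.22 at 22 °C and 6.15 to 6.26 at 6 °C, with no clear rise. The macrophage score was 2.56 to 3.05 at 22 °C and 3.56 to 4.26 at 6 °C. These values argue against a lower adipocyte share as the whole cause of the macrophage rise at 6 °C. Over libraries, the macrophage minus endothelial score changed by -1.36 from 30 to 22 °C and by 0.92 from 22 to 6 °C. The exact permutation p was 0.0286 for each step over 70 assignments of the libraries, and 0.343 for 6 °C against 30 °C. The lowest of the 3 list medians was 2.62 without 22 °C mouse 3, the deep library, 1.90 without 30 °C mice A and B, whose mouse is unknown, and 2.34 after removal of the exon length and GC trend, which argues against each as the whole cause. Fewer or less active immune and dividing cells at 22 °C, which the design links to temperature, stays open as a hypothesis, as does an unrecorded difference in housing or handling between the groups.

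Genes of the nuclear-encoded respiratory chain were highest at 22 °C. Removal of the length and GC trend left a median difference of the steps of -0.86 with 55 of 62 members called. The list lay -0.44 from the median of 10000 random lists matched on expression and exon length. Without 22 °C mouse 3 the median was -0.95. These values argue against these as the whole cause. The matched lists themselves had a median of -0.44, so short abundant genes as a class shared the direction. Cytosolic ribosomal protein genes, which are also short, had -0.34 (spread 0.06). This lies between the limits set for a shared and for a separate shape, which were chosen after the results were seen. At 22 °C against 30 °C their median was -0.05 (5 higher and 9 lower of 79), while most respiratory genes rose, so that rise was not shared. At 6 °C against 22 °C both groups fell (ribosomal median -0.44). A process common to both at that step cannot be told apart from separate ones. A response of respiratory genes to temperature stays open.

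Skeletal muscle markers were uneven between libraries. Myh4 stood at 1173 CPM in 30 °C mouse 1, 1017 in 22 °C mouse 4 and 1.35 in 6 °C mouse 3. Within groups the markers rose and fell together (median pair correlation 0.98), which is consistent with varying amounts of muscle taken with the depot. Temperature stays open as a further source (exact permutation p = 0.257 for 6 °C against 30 °C). With the muscle marker level as a covariate 7108, 6516 and 3736 genes changed in the pairs of temperatures.

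Other ways of splitting the 8 libraries of each pair were tried. For 6 °C against 30 °C, 1 of 35 splits, the real one, gave as many genes (8444 with all libraries in the fit, highest other 17). It was 1 of 35 for 22 °C against 30 °C (6634, highest other 0) and for 6 °C against 22 °C (5091, highest other 1). No smaller share than 1 of 35 can arise. Each other split puts mice of both temperatures in each group, so any real difference widens the spread within groups. The few calls there therefore cannot show how many genes chance alone would call. Over 12 libraries 1 of 100 splits gave as many genes for any temperature (9770, highest other 4400). For the difference of the steps there were 2 of 100 (4353, highest other 4715). Those splits also mix the temperatures, so their counts carry the same limit. For the difference of the steps the share lies under the limit of 1 in 20 set beforehand. Yet another split called more genes than the real groups, so chance was not excluded for that count. The same split also called 3308 genes for any temperature. What sets it apart was not tested. The real groups with 30 °C or 6 °C set as the middle of the steps, where 8323 and 7052 genes were called, were not counted as separate splits, a choice made after a first draw was seen. Called lists were different: 11 of 35 splits gave as many lists for 6 °C against 30 °C (20, highest other 24). There were 11 of 35 for 22 °C against 30 °C (20, highest other 22) and 9 of 35 for 6 °C against 22 °C (12, highest other 17). Chance could not be excluded for the number of called lists.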

How the results depend on the processing

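The thinned, paired-omission and length and GC settings were chosen after seeing the data, and the others before. The counts of 8444 (6 °C against 30 °C), 6634 (22 °C against 30 °C), 5091 (6 °C against 22 °C), 9770 (any temperature) and 4353 genes (difference of the steps) stayed within 1.5 times their value under every other scaling, filter, tool and spread setting, with the muscle covariate (7108, 6516, 3736, 8764 and 3952) and in the added settings, with these exceptions. A threshold of 2-fold left 2716, 1870, 1326, 3523 and 2193, and glmTreat against 1.5-fold left 2693, 1613, 696 and 1506, and was not run for any temperature. An adjusted p under 0.01 left 2803 genes for 6 °C against 22 °C and 2236 for the difference of the steps. These 3 settings ask for more of each gene by construction. With the mouse number as a block, which leaves out 30 °C mice A and B, 3245 genes were called for 22 °C against 30 °C, 2468 for the difference of the steps and 2209 in the overlap of both comparisons with 30 °C. Without mice A and B and with no block, 6570, 4454, 5316, 8194 and 3376 genes were called and 3065 in the overlap, so fewer libraries at 30 °C make up part of these drops, and the cause of the rest was not tested. In that setting Ucp1 (adjusted p = 0.0611), Gk (0.0534), Mlxipl (0.123), Dio2 (0.0977) and Slc2a1 (0.0858) were not called for 22 °C against 30 °C, nor Pdk4 (0.0672), Nrg4 (0.0508) and Hspb1 (0.0727) for 6 °C against 30 °C. The numbers do not pair the mice: the correlation of deviations of same-numbered libraries had a median of 0.01 and was above 0.1 in 3 of 8 pairs. Leaving out 1 library gave 7578 to 8656, 5479 to 6630, 4150 to 5310, 8970 to 9784 and 3317 to 4711 genes. Of 9010 alternative values of 282 named gene results, 8767 kept direction and side of the threshold, 204 lost the call, 38 gained it and 1 reversed: Akt1 at 6 °C against 30 °C, which did not pass (0.02), fell by 0.29 on the log2 scale with total counts only, and the cause was not tested. Of the lost calls 129 fell to the fold and strict thresholds, 21 to the block and 7 to total counts. The list calls (20, 20, 12 and 12) were all lost with an estimated correlation (0 in every comparison), and fry called 25, 26, 10 and 14, which at 6 °C against 22 °C lost 5 calls (the TCA cycle, the respiratory chain, interferon, macrophages and skeletal muscle) and gained 3. Without 1 library 20 to 21, 19 to 23, 10 to 14 and 12 to 14 lists were called. Simulations used these library sizes, 4 mice per group and the estimated spread. For 6 °C against 30 °C they recovered 28% of genes changed by 0.5 on the log2 scale. They changed far fewer genes than were called in the data, so that share need not hold for the data. Depth, group size and spread were not varied apart.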

Other observations

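The gene groups for the macrophages below and the ribosomal protein set were chosen after values of some of their members had been seen, and the tests on them were chosen then too. Cytosolic ribosomal protein genes, a group outside the 35 lists, were lowest at 6 °C. Of 79 tested, 49 were lower and 3 higher at 6 °C than at 30 °C (median -0.52), 44 lower and 3 higher than at 22 °C (median -0.44), and 9 lower and 5 higher at 22 °C than at 30 °C (median -0.05), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The 6 °C medians stayed negative under RLE (-0.47 against 30 °C), upper-quartile (-0.59), total-count (-0.84) scaling and after removal of the exon length and GC trend (-0.39), while the median at 22 °C against 30 °C turned to 0.02 in the last. Eif4ebp1, a repressor of translation initiation, stood at 107 ± 12, 210.3 ± 16.2 and 127 ± 5.8 CPM at 30, 22 and 6 °C, and Mtor at 107 ± 12.1, 186 ± 18.9 and 421 ± 54.9.

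Clock, early-response and erythrocyte genes were not called as groups at 6 °C. In the circadian clock list 6 of 19 genes rose and 2 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.189, adjusted p = 0.571 with an estimated correlation) between 30 °C and 6 °C. Bhlhe40 stood at 2.42, and with total counts only 1 member was higher and 4 lower. The time of day of tissue collection is not given in the sources used here. In the immediate early and heat shock list 3 of 20 genes rose and 2 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.68, adjusted p = 0.914 with an estimated correlation). Hspb1 rose by 0.58, a call lost with total counts only and without 30 °C mice A and B (adjusted p = 0.0727). Erythrocyte markers did not pass: 0 of 5 genes passed (the same adjusted over the list alone, camera adjusted p = 0.886, adjusted p = 0.937 with an estimated correlation). Their median of 0.09 turned to -0.22 with total counts only.

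Of the macrophage genes that fell at 22 °C, some rose at 6 °C and others did not. A group of 12 genes of lipid-handling macrophages (among them Trem2, Gpnmb, Spp1, Mmp12, Itgax and Atp6v0d2) had a median log2 fold change of -4.35 at 22 °C against 30 °C and 3.06 at 6 °C against 22 °C, with 10 of 12 rising in the latter. Its score (mean log2 CPM) at 30 °C was 4.20 and 4.90 in mice 1 and 2 and 6.42 and 6.33 in mice A and B, against 2.13 to 2.88 at 22 °C. Without 30 °C mice A and B the medians were -2.65 and 3.06, with 9 of 12 lower and 1 higher at 22 °C than at 30 °C. A group of 11 tested genes of resident macrophages (among them C1qa, C1qc and Mrc1) had medians of -0.74 and 0.08, with 0 rising and 2 falling at 6 °C against 22 °C. Without 30 °C mice A and B the resident medians were -0.77 and 0.09, with 2 rising and 1 falling at 6 °C against 22 °C. Of these groups, 4 and 6 genes also stand in the macrophage list. The difference between the mean log2 CPM of the groups was larger at 6 °C than at 22 °C by 2.46 (2.29 to 2.64 with 1 library left out; exact two-sided permutation p = 0.0286 over 70 assignments of the 8 libraries, the smallest this design gives). Because 8 genes of the first group and 3 of the second were picked after their values had been seen, this test cannot decide whether lipid-handling macrophages return in severe cold while resident ones do not. With those genes left out the difference was 0.63 (4 and 8 genes, exact permutation p = 0.0286), and the 4 left in the first group (Cd9, Ctsd, Cd63 and Lipa) are lysosomal or membrane genes that other cells of the depot also express, so the hypothesis that the kind of macrophage may differ between 22 °C and 6 °C stays open.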
